A study of Mycobacterium marinum with 8 samples.

How the data were processed

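Total RNA was taken from 8 cultures of the Mycobacterium marinum M strain, wild type per the labels, grown in 7H9 medium with ADS supplement and tyloxapol. Compound 8, also labelled 8-73, or DMSO was added at a labelled 10 or 20 µM. Per the labels, RNA was isolated with a NucleoSpin kit after bead beating, ribosomal RNA was depleted with RiboMinus, and a service provider sequenced the libraries. The series text names the removal of low-quality reads and alignment to an M. marinum reference with CLC Genomics Workbench. The submitters' processing notes name bcl2fastq 2.18 and TopHat2 2.1.1, and also mouse genome builds that do not match the M. marinum coordinates of the values. Which tool wrote the gene values is not given in the sources used here.

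The deposited values are FPKM per gene, in a Cufflinks-style layout with confidence bounds and a status for each gene, and the same 5668 genes are listed for all 8 libraries. Counts and strand are not given in the sources used here, so reads of antisense transcripts, overlapping genes and paralogs could not be separated. Of the genes, 328 have a symbol, and all others carry a tag only. Starts and ends are 1-based positions on the deposited chromosome or plasmid. Fragments behind each value were estimated as 4 times the squared ratio of FPKM to the distance of its upper bound, taking the bounds as 95% limits. Of the 6339 estimates under 50 fragments, 37.8% lay within 0.05 of a whole number, so these are estimates. They cover no spread between cultures, and they did not follow FPKM in every gene. From DMSO to compound replicate 1 at 10 µM, leuC went from 85.9 to 204 scaled FPKM and from 960 to 2317 fragments. For eccA at 636369, which overlaps its neighbour eccB, scaled FPKM went from 449 to 177 and fragments from 1743 to 1246. The bounds of such a gene do not reflect counting error alone, and the cause was not tested.

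Implied mapped fragments were, in M (mega) fragments, 8.57 and 8.48 in the DMSO libraries labelled 10 µM (replicates 1 and 2), 8.65 and 8.87 in the 10 µM compound libraries, 12.5 and 6.40 in the DMSO libraries labelled 20 µM, and 10.8 and 10.1 in the 20 µM compound libraries. Fragments in tested genes, summed from the estimates for each gene, were 3.72, 3.41, 3.54, 3.71, 5.90, 2.61, 4.91 and 4.56 M in the same order.

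Left out were 4 genes: the 5S ribosomal RNA gene rrf, 2 long genes beside it that have no estimate in any library, and ssrA, which has no estimate in 5 libraries. Another 53 genes had a mean FPKM under 1, which left 5611 genes, 5583 on the chromosome and 28 on the plasmid. FPKM were scaled between libraries by a trimmed mean of log2 ratios (30% trimmed at each end, unweighted, with factors from 0.845 to 1.16). The log2 of scaled FPKM plus 1 was fitted in limma 3.58.1 (R 4.3.3) with the 4 groups as levels over all 8 libraries, 4 residual degrees of freedom, and a trended, robust estimate of the spread. This scale understates changes of genes with low FPKM. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over genes at 0.05. The 4 comparisons were compound against DMSO at 10 µM, the same at 20 µM, the difference of these responses (20 minus 10 µM), and the DMSO groups (20 minus 10 µM). The 10 and 20 µM comparisons share no library.

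The comparisons, the limma fallback for normalized values, the gene lists, the rule for named genes and most of the other settings were fixed before the data were examined. Because so few genes have a symbol, the rule was narrowed afterwards. For each compound comparison it names the 10 largest rises and falls with a symbol (5 in the other comparisons) that passed, with mean FPKM of at least 10 and libraries that do not overlap between groups, and 2 genes with a tag per direction. To these it adds up to 3 passing members of each list and a fixed set of genes. Of 27 fixed lists, 10 had no matched gene: PE and PPE families, iron, DosR, NADH dehydrogenase I, mycolic acids, PDIM and phenolic glycolipids, cell wall stress and efflux, sigma factors, zinc and copper, and Mce transport. The zinc and copper list names numbered copies of rpmB, rpmG and rpsR. These symbols are listed without a number, so such copies could not be matched and were counted with the ribosomal proteins. ESX clusters were assigned from the order of symbols along the chromosome after the values were seen and before any test, and an ESX-4 list was added then. The 15 lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry.

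Other settings were other scalings (median of ratios, upper quartile), no filter, pseudocounts of 0.1 and 5, ribosomal RNA genes kept, the replicate number as a block, fits on the 4 libraries compared, and each library left out in turn. Added after the data were seen were the values without rescaling, voom on the implied fragments, and genes of at least 200 bp. With 1 library left out, the lone library of its group is assumed to vary like the others.

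The fit was tested on simulated data with the residual spread of the genes, with 100 genes changed 2-fold and 100 changed 4-fold in each of 5 simulations. It called 77% of the 2-fold and 94.2% of the 4-fold changes, none with the wrong sign, and 0.170% of unchanged genes. The changed genes were drawn from those with mean FPKM of at least 10, so recovery of lower genes was not covered. With no gene changed it made 0 calls. Noise was drawn independently for each gene and library, so spread shared between genes or within a set of cultures was not simulated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.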

Results

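RNA was sequenced from 8 cultures of Mycobacterium marinum, a relative of the tuberculosis bacillus that infects fish. The cultures were of the wild-type M strain and received compound 8, a small molecule known here only by its code, or its solvent DMSO. The labels give compound and DMSO cultures a concentration of 10 µM or 20 µM, which makes 4 groups of 2 libraries each, described as biological duplicates. The 10 µM and 20 µM compound cultures therefore have separate DMSO cultures, and DMSO carries the concentration of the compound it was set against. Each library lists an FPKM value (fragments per kilobase of gene, normalised to the mapped fragments of the library) for 5668 genes, 5640 on the chromosome and 28 on a plasmid. The confidence bounds listed beside each FPKM imply 6.40 to 12.5 M (mega) mapped fragments per library. The fragments estimated from these bounds for the 5611 genes tested summed to 40.2% to 47.2% of that, which is not a counted share. Replicates correlated across genes with Pearson r of 0.965 to 0.974 on the log2 scale. The estimated fragments of replicates gave a chi-square per degree of freedom of 4.08 to 10.3. This does not decide whether replicates differed beyond counting noise, since the estimates do not follow FPKM in every gene. In the 20 µM DMSO libraries, eccA at 636369 had scaled FPKM of 219 and 211, from an estimated 1663 and 1138 fragments. The gene katG had 238 and 237 there, from an estimated 7551 and 3124 fragments. On a principal component plot, the first component (33.9% of the variance) separated libraries labelled 10 µM from those labelled 20 µM, and the second (24.9%) placed compound libraries on the other side of their DMSO libraries. All levels below are scaled FPKM as mean ± SD with n = 2, and changes are log2 fold changes of scaled FPKM plus 1 with their SE. Adjusted p-values are from limma.

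The first comparison asks which transcripts responded to compound 8 at 10 µM. The gene lon, which encodes an ATP-dependent protease, rose from 11.0 ± 1.00 to 136 ± 18.3 (log2 fold change 3.52 ± 0.15, adjusted p = 1.24e-05). It lies at 3353614 to 3355956 on the chromosome, and at least 170 fragments stood behind each of its values. The thioredoxin system rose with it: trxB (6626782 to 6627780), thioredoxin reductase, went from 177 ± 3.98 to 880 ± 66.3 (2.30 ± 0.10, adjusted p = 1.24e-05). Of the genes named trxA, the thioredoxin gene at 2741615 to 2741944 rose by 1.78 ± 0.24 (adjusted p = 0.00306), and the copy beside trxB at 6627777 to 6628130 by 0.91 ± 0.12 (adjusted p = 0.00249). The arsenite efflux gene arsB (2479478 to 2480995) rose from 21.0 ± 1.21 to 119 ± 8.46 (2.45 ± 0.12, adjusted p = 2.16e-05).

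The other 6 of the 10 largest rises among genes with a symbol were those of clpB, leuC, leuD, fbiC, merA and ffs. The disaggregase gene clpB (778180 to 780726) rose from 36.5 ± 1.29 to 79.7 ± 7.67 (adjusted p = 0.000910). The neighbouring leucine synthesis genes leuC (2078579 to 2080000) and leuD (2080025 to 2080621) rose by 1.17 ± 0.09 and 1.13 ± 0.22 (adjusted p = 0.000266 and adjusted p = 0.0132). The gene fbiC (5271556 to 5274126), of cofactor F420 synthesis, rose by 0.98 ± 0.09 (adjusted p = 0.000555). The mercuric reductase gene merA, on the plasmid at 12901 to 14319, went from 7.33 ± 1.61 to 14.6 ± 2.06 (0.91 ± 0.20, adjusted p = 0.0228). The 97 bp gene ffs (6331090 to 6331186), for the RNA of the signal recognition particle, rose by 1.18 ± 0.21 (adjusted p = 0.00822), with as few as 38.9 fragments behind a value.

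Larger rises belonged to genes that the files give by tag only. MMAR_RS02325 (554570 to 555385) went from 8.47 ± 2.13 to 703 ± 96.6 (6.23 ± 0.20, adjusted p = 7.39e-06). MMAR_RS01140 (266145 to 266357) was at 3.09 and 0 in the DMSO libraries, below 1 estimated fragment in each, and at 133 and 150 in the compound libraries (adjusted p = 0.00597). Of the genes with a tag only, the largest fall under the naming rule was that of MMAR_RS10720 (2594503 to 2595288), from 239 ± 41.6 to 27.0 ± 6.22. It fell by 3.10 ± 0.20 on the log2 scale (adjusted p = 7.35e-05), and MMAR_RS10715 beside it (2593868 to 2594410) fell by 2.57 ± 0.16 (adjusted p = 7.47e-05).

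Genes of ESX-3, one of the type VII secretion systems that export proteins across the mycobacterial cell envelope, fell together at 10 µM. In the ESX-3 region (636369 to 651141), 9 of 11 genes fell, 10 when adjusted over the list alone, and the other 2 also had negative values. The median of the list was -0.87, and its camera test gave adjusted p = 4.25e-06, but adjusted p = 0.583 with an estimated correlation. The membrane and ATPase components eccA (636369 to 638210) and eccB (638207 to 639808) fell by 1.17 ± 0.11 and fell by 0.95 ± 0.21, and the protease gene mycP (648714 to 650138) fell by 0.90 ± 0.23. The genes eccD (647299 to 648717) and eccE (650128 to 651141) each fell by 0.87, with SE of 0.17 and 0.20. Adjusted p-values of these 5 genes ran from 0.000690 for eccA to 0.0361 for mycP. The 10 µM DMSO replicates 1 and 2 lay apart, at 449 and 362 (eccA), 298 and 179 (eccB), 152 and 107 (eccD), 151 and 92.9 (mycP) and 158 and 97.2 (eccE). In the same order, the 10 µM compound replicates were at 177 and 180, 124 and 114, 70.1 and 68.3, 67.2 and 59.1, and 67.5 and 67.1. Between the DMSO groups (20 minus 10 µM) the list median was -0.24, with 9 of 11 values negative and 1 gene passing (camera adjusted p = 0.193). There eccA was at -0.91 ± 0.11, so its fall cannot be told apart from a high level in the 10 µM DMSO cultures. The values of eccB, eccD, mycP and eccE were -0.53 ± 0.21, -0.00379 ± 0.17, 0.01 ± 0.23 and -0.08 ± 0.20, and none passed.

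In the ESX-5 region (3249090 to 3269748), 7 of 16 genes fell and none rose, 7 also when adjusted over the list alone. The list median was -0.33, with adjusted p = 0.00202 and adjusted p = 0.583 with an estimated correlation. Its eccD (3263480 to 3264991) fell by 0.59 ± 0.10 (adjusted p = 0.00633), eccE (3266708 to 3267919) fell by 0.42 ± 0.12 (adjusted p = 0.0479) and mycP (3264969 to 3266711) fell by 0.35 ± 0.08 (adjusted p = 0.0280). The first gene of the region, eccB (3249090 to 3250613), had a value of -0.07 ± 0.12 (adjusted p = 0.760). In the ESX-1 region (6582254 to 6605653), 2 of 20 genes fell, 1 when adjusted over the list alone, with a list median of -0.16 and adjusted p = 0.137. The 3 genes of the ESX-4 region had a median of 0.19 and none passed (list adjusted p = 0.805).

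**Figure D1:**
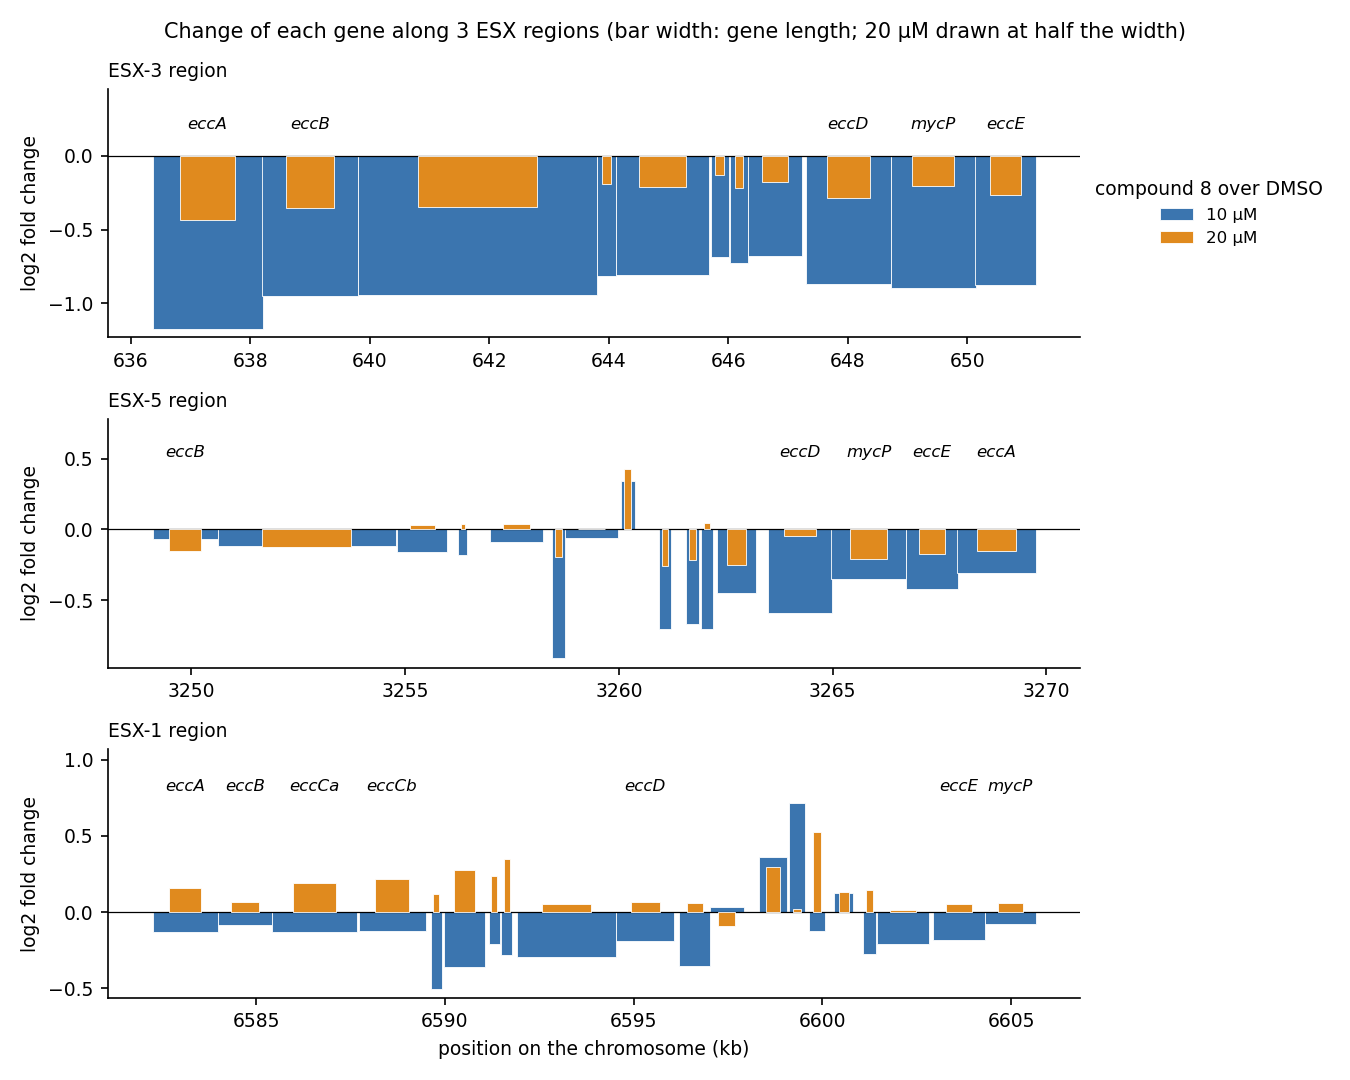
Log2 fold change of each gene (compound 8 over DMSO) along the ESX-3, ESX-5 and ESX-1 regions of the chromosome, with position in kb on the horizontal axis. Wide bars are the 10 µM comparison and narrow bars the 20 µM comparison, drawn over each gene; all 11 ESX-3 genes lie below 0 in both, with medians of -0.87 and -0.22.

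Ribosomal protein genes also fell at 10 µM. Of the 16 with a symbol, 8 fell, 12 when adjusted over the list alone, and all 16 had negative values. The list median was -0.56 (adjusted p = 3.20e-05, adjusted p = 0.154 with an estimated correlation). The same list differed more between the DMSO groups (20 minus 10 µM, median -0.95, 11 of 16 lower). For example, rplS was at 2868 ± 390 in the 10 µM DMSO, 1719 ± 50.1 in the 10 µM compound and 1187 ± 50.6 in the 20 µM DMSO libraries. A fall under compound 8 therefore cannot be told apart from a high level in the 10 µM DMSO cultures. One example is rpmB at 332664 to 332900, for a copy of protein L28, which fell by 1.89 ± 0.37 (adjusted p = 0.0160). An estimated 34 to 205 fragments stood behind its values at 10 µM. The other rpmB copy, at 2092492 to 2092686, was at -0.30 ± 0.29 and did not pass (adjusted p = 0.546). The L19 gene rplS (2201131 to 2201472) fell by 0.73 ± 0.13 (adjusted p = 0.00822), and the S18 gene rpsR at 74400 to 74654 fell by 0.63 ± 0.12 (adjusted p = 0.0125). The heat shock and protein folding list held 3 genes, clpB and both copies of the chaperonin gene groL, and all 3 rose (median 0.62, adjusted p = 0.00202, adjusted p = 0.187 with an estimated correlation). Its groL at 913752 to 915377 rose by 0.62 ± 0.10 (adjusted p = 0.00507) and the copy at 1349333 to 1350952 by 0.43 ± 0.11 (adjusted p = 0.0320).

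The other lists did not pass camera at 10 µM, while the redox and the Clp protease and proteasome lists passed fry (adjusted p = 0.00925 and adjusted p = 0.00114), which does not compare a list with other genes. In the redox list, trxB and both trxA rose, 12 of 15 genes did not pass, and 2 further genes fell when adjusted over the list alone. Its mean was 0.25 and its median -0.07, which turned to 0.06 without rescaling (adjusted p = 0.628). In the Clp protease and proteasome list, lon was the 1 gene of 5 that rose (median 0.00324, mean 0.65, adjusted p = 0.628). The signal peptidase gene lepB (2201584 to 2202447) fell by 0.61 ± 0.12 (adjusted p = 0.0117) and was the 1 gene of 6 in the Sec and Tat export list to pass (median 0.000231, mean -0.09, adjusted p = 0.805). No gene passed limma or voom in the lists for the DNA damage response (7 genes, median 0.20, adjusted p = 0.628), sulfur assimilation (8 genes, 0.13, adjusted p = 0.628) and the propionate, glyoxylate and TCA cycle (4 genes, 0.17, adjusted p = 0.628). The same held for arabinogalactan and peptidoglycan synthesis (3 genes, -0.05, adjusted p = 0.628), ATP synthase (3 genes, -0.02, adjusted p = 0.987) and the cytochrome oxidases (5 genes, median -0.09, mean 0.00749, adjusted p = 0.883). Without rescaling the medians of these last 3 lists turned to 0.08, 0.10 and 0.03, and with upper-quartile scaling that of ATP synthase to 0.02. At unadjusted p under 0.05 there were 2 genes of the TCA cycle list, 1 each of the DNA damage, sulfur and arabinogalactan lists, and 0 of the ATP synthase and cytochrome lists. Lists with fewer than 3 matched genes were not tested: in nitrogen metabolism gltD (6544333 to 6545799) rose by 0.39 ± 0.09 (adjusted p = 0.0225), and neither higA of the toxin-antitoxin list nor the 2 phoU copies of the phosphate list passed over all genes. When adjusted over the list alone, 1 phoU and 1 arabinogalactan gene fell, and 2 nitrogen metabolism genes rose. The DNA repair gene recA was at 0.32 ± 0.14 (adjusted p = 0.176) and the catalase-peroxidase gene katG at -0.07 ± 0.10 (adjusted p = 0.707). Outside these lists, the metal-transporting ATPase gene cadA (2739119 to 2741098) fell by 0.79 ± 0.12 and panB (4071163 to 4071999), of pantothenate synthesis, fell by 0.71 ± 0.12 (adjusted p = 0.00480 and adjusted p = 0.00664).

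Over all 5611 genes, 903 changed at 10 µM, 374 of them higher and 529 lower (41.4% higher), and 270 changed by at least 2-fold (158 higher, 112 lower). Of the 325 tested genes with a symbol, 54 changed, 28 higher and 26 lower. Without rescaling between libraries, 496 genes changed and 58.5% of them were higher. Of the lists, 0 of 16 ESX-5 genes, 2 of 11 ESX-3 genes and 2 of 16 ribosomal protein genes passed, and list medians relative to all genes were -0.32, -0.86 and -0.54. The count was 546 without compound replicate 1 at 10 µM and 407 without replicate 2. Leaving out either of these ended the calls of leuD (highest adjusted p 0.0730), lepB (0.0618) and the ESX-3 genes eccB (0.121), eccD (0.0794) and eccE (0.110). Leaving out replicate 1 ended those of rpmB (0.0759) and rpsR (0.0650), and replicate 2 those of ffs (0.0558), rplS (0.0597) and the ESX-5 list. Without either, or without DMSO replicate 2 at 10 µM, merA lost its call (0.140). The ESX-3 mycP (0.174), groL at 1349333 (0.147) and gltD (0.113) lost theirs when any 1 compound library, at 10 or 20 µM, was left out. The same held for mycP without DMSO replicate 1 at 10 µM, groL without DMSO replicate 2 at 10 µM and gltD without either DMSO library at 10 µM. The ESX-5 mycP lost its call without any 1 of the 8 libraries (0.135) and eccE without any except DMSO replicate 2 at 10 µM (0.198), and the ESX-1 list passed without compound replicate 1 at 10 µM. By voom the ESX-3 eccA (at -0.54, adjusted p = 0.0674) and the ESX-5 eccD (at -0.38, adjusted p = 0.210) did not pass, and without rescaling panB did not (adjusted p = 0.0540). In the main fit eccA was at -1.17 and eccD at -0.59. Since voom rests on the implied fragments, which did not follow FPKM for these 2 genes, its values do not decide about them.

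**Figure D2:**
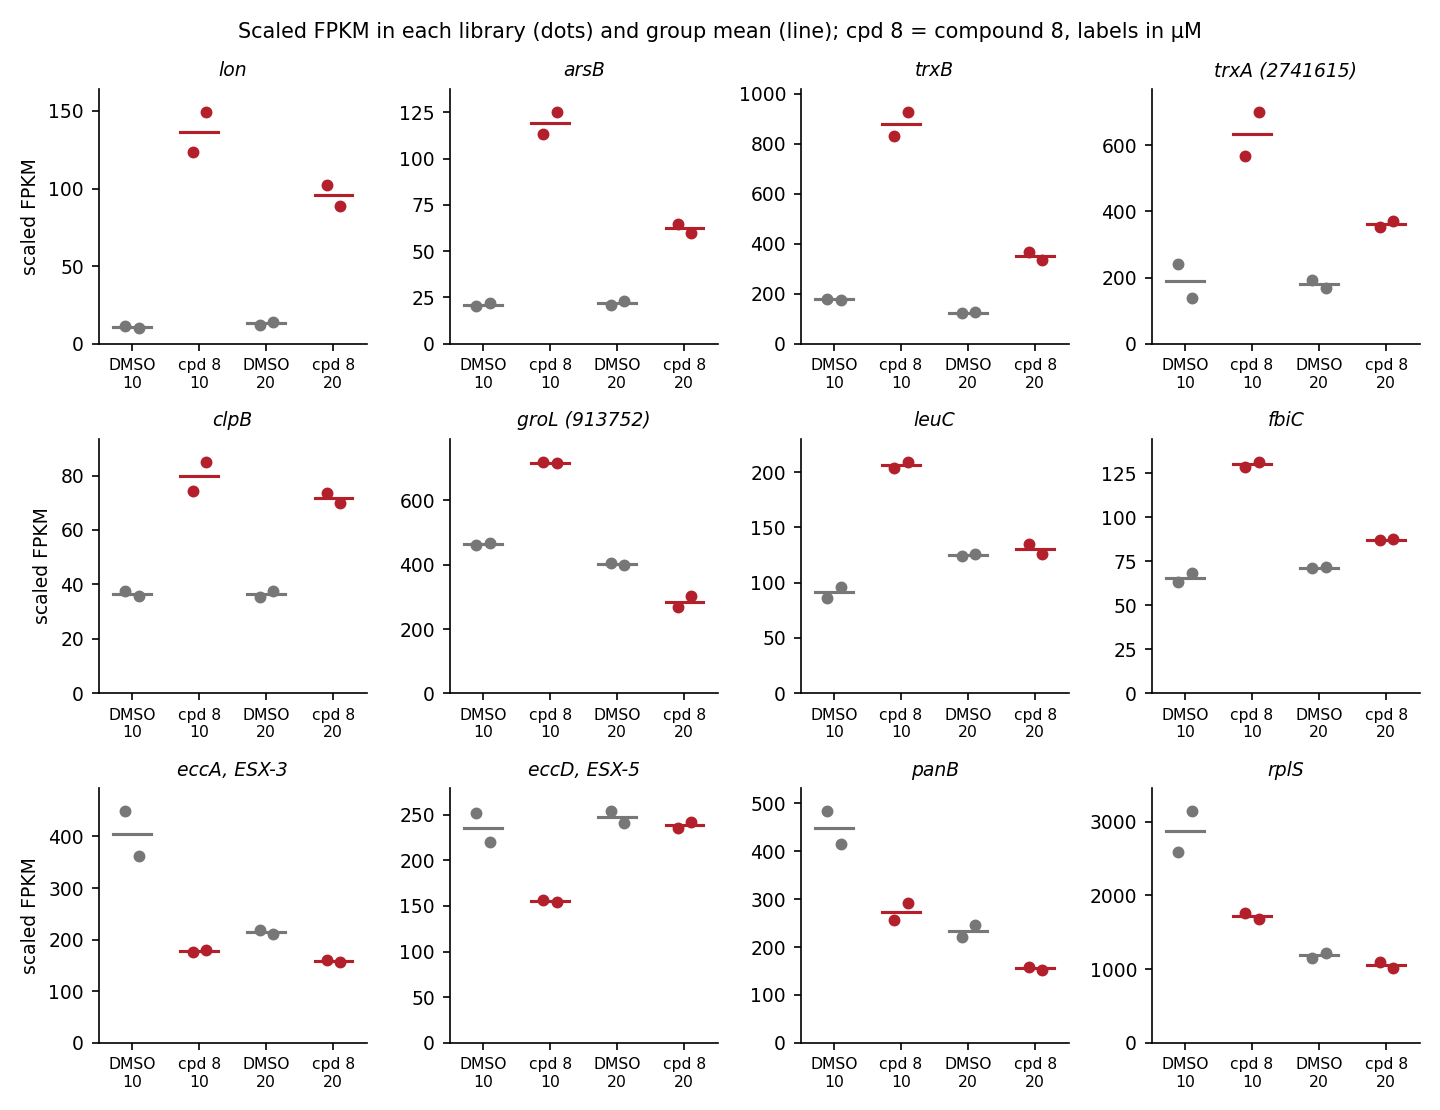
Scaled FPKM of 12 named genes in each of the 8 libraries (dots) with the mean of each group (line), grey for DMSO and red for compound 8, by labelled concentration in µM. In the lon panel the DMSO libraries lie between 10.3 and 14.2 and the compound libraries between 89.0 and 149.

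The second comparison asks the same question at 20 µM, against the DMSO cultures of that label. Among genes with a symbol, the largest rises were again those of lon, trxB and arsB. lon rose from 13.2 ± 1.45 to 95.6 ± 9.30 (log2 fold change 2.77 ± 0.15, adjusted p = 7.91e-05). trxB rose from 123 ± 2.86 to 350 ± 24.3 (adjusted p = 0.000217), and arsB from 21.9 ± 1.43 to 62.4 ± 3.65 (1.47 ± 0.12, adjusted p = 0.000658). clpB rose by 0.95 ± 0.11 (adjusted p = 0.00409) and ffs by 1.16 ± 0.21 (adjusted p = 0.0290). MMAR_RS02325 rose from 5.54 ± 1.45 to 652 ± 9.33 (6.66 ± 0.20, adjusted p = 8.88e-06), a larger change than theirs. MMAR_RS01140 was at 3.57 and 13.3 in the DMSO libraries, from an estimated 1 and 2 fragments, and at 230.0 and 218 in the compound libraries (adjusted p = 0.0410).

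Of the genes with a symbol, 2 fell at 20 µM. panB fell by 0.58 ± 0.12 (adjusted p = 0.0459), and groL at 913752 to 915377, which rose at 10 µM, fell by 0.49 ± 0.10 (402 ± 4.44 in DMSO, 285 ± 23.5 in the compound libraries, adjusted p = 0.0380). With a tag only, MMAR_RS28315 (2976031 to 2976414) fell from 226 ± 27.0 to 47.7 ± 14.5 (fell by 2.25 ± 0.30, adjusted p = 0.00854), and in the DMSO cultures it was higher at the 20 µM label (1.63 ± 0.30). MMAR_RS10720, named for its fall at 10 µM, fell by 1.39 ± 0.20 (adjusted p = 0.00876). MMAR_RS04750 (1181287 to 1181363, 77 bp) was listed at 0 in every library except the DMSO libraries labelled 20 µM, where it stood at 278 and 653, each from an estimated 2 fragments (adjusted p = 2.93e-05, and adjusted p = 0.257 by voom on fragments implied by the listed bounds). The trxA at 2741615 was at 1.00 ± 0.24 and did not pass (adjusted p = 0.0790). leuC was at 0.06 ± 0.09 (adjusted p = 0.856), fbiC at 0.29 ± 0.09 (adjusted p = 0.179), recA at -0.18 ± 0.14 (adjusted p = 0.675) and katG at 0.14 ± 0.10 (adjusted p = 0.619).

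No gene of an ESX region passed limma at 20 µM, and 3 lists did by camera. ESX-1 genes had a median of 0.13 with 19 of 20 values positive (adjusted p = 0.00887), ESX-3 genes a median of -0.22 with 11 of 11 negative (adjusted p = 0.0244), and ribosomal protein genes a median of -0.21 with 13 of 16 negative (adjusted p = 0.0394). With an estimated correlation the value was adjusted p = 0.693 for each of the 3. None of their members passed limma, over all genes or when adjusted over the list alone. At unadjusted p under 0.05, 3 ESX-1, 2 ESX-3 and 5 ribosomal protein genes did, and by voom 1 ESX-1 gene passed. By fry none of these 3 lists passed (adjusted p = 0.189 for ESX-1, 0.329 for ESX-3 and 0.156 for ribosomal proteins). None of the 3 lists passed camera without DMSO replicate 1 or compound replicate 1 at 20 µM, and the ribosomal protein list did not without compound replicate 2. ESX-5 had a median of -0.14 (adjusted p = 0.286, with 2 genes at unadjusted p under 0.05), and its eccB, eccD, eccE and mycP were at -0.15 ± 0.12, -0.05 ± 0.10, -0.17 ± 0.12 and -0.21 ± 0.08 and did not pass (for the first 3, adjusted p = 0.681, 0.894 and 0.584). In the heat shock list clpB rose and 1 groL fell, 2 when adjusted over the list alone (median -0.29, mean 0.06, adjusted p = 0.715). In the redox list trxB alone passed over all genes (median -0.02, 0.05 without rescaling, mean 0.12, adjusted p = 0.594), 2 genes when adjusted over the list alone. In the Clp protease and proteasome list lon alone rose (median -0.00208, 0.07 without rescaling and 0.01 with upper-quartile scaling, mean 0.55, adjusted p = 0.286, and adjusted p = 0.00349 by fry). The remaining 8 tested lists had no gene passing limma or voom and adjusted p from 0.573 to 0.894, among them sulfur assimilation (median -0.13, mean 0.01) and the propionate, glyoxylate and TCA cycle (median -0.00155, mean 0.00895). The median of the latter turned to 0.07 without rescaling and 0.01 with upper-quartile scaling, and that of the Sec and Tat export list from -0.04 to 0.03 without rescaling.

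**Figure D3:**
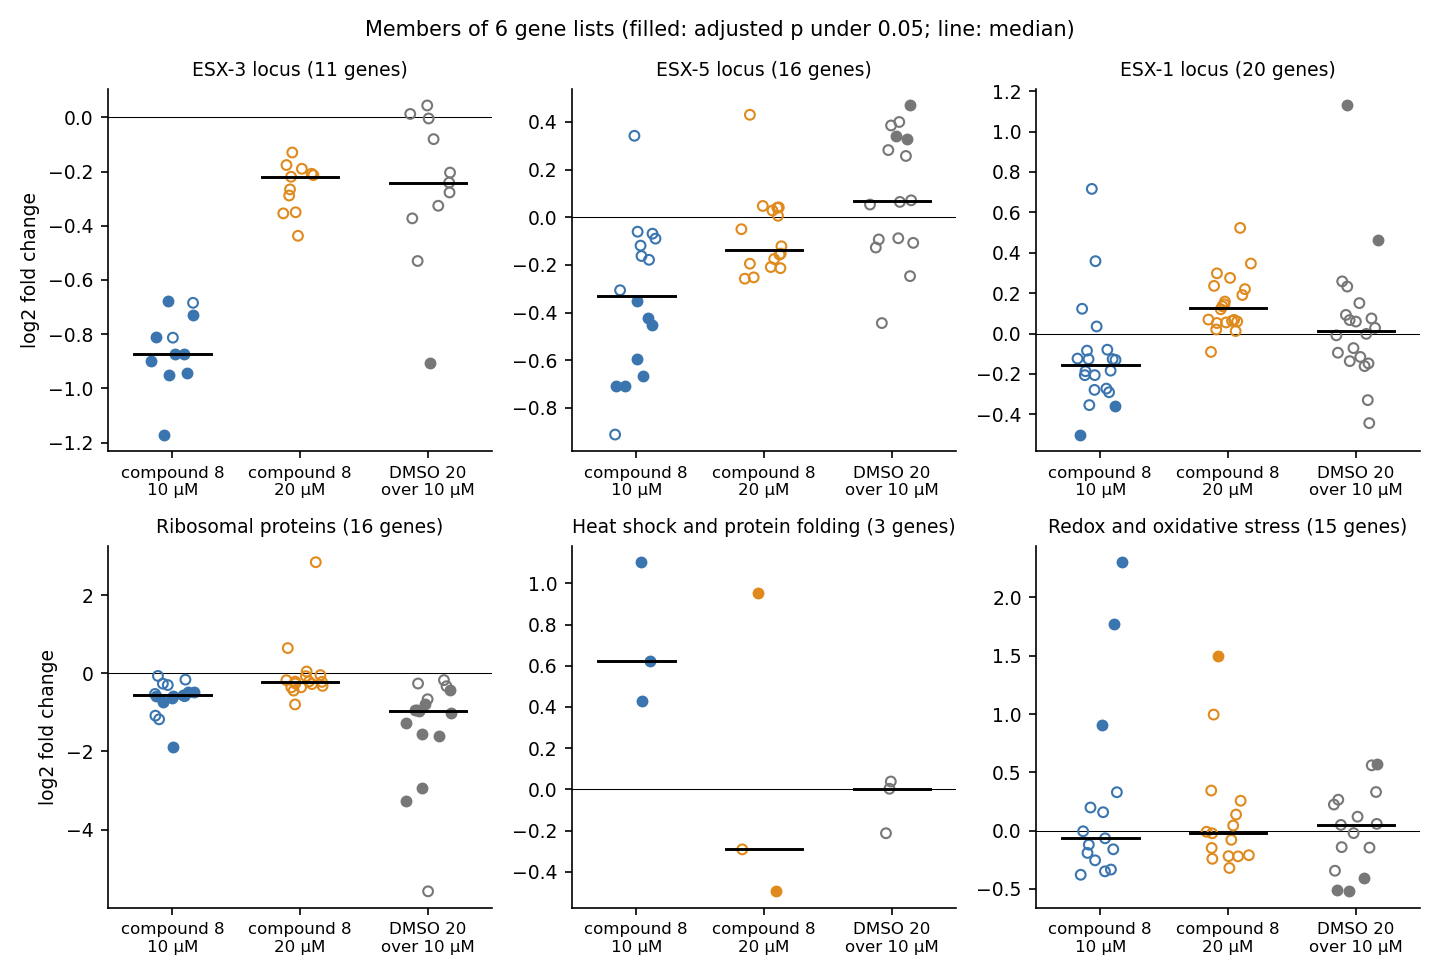
Log2 fold change of each member of 6 gene lists at 10 µM, at 20 µM and between the DMSO groups (20 over 10 µM), with filled circles for adjusted p under 0.05 and a line at the list median. The ESX-3 list has medians of -0.87 and -0.22 at the 2 concentrations, and the ribosomal protein list a median of -0.95 between the DMSO groups.

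In all, 168 genes changed at 20 µM, 106 higher and 62 lower (63.1% higher), 101 by at least 2-fold (82 higher, 19 lower), and 7 with a symbol. Without rescaling, 126 genes changed and 77.8% were higher. The count was 68 without compound replicate 1, 85 without compound replicate 2 and 79 without DMSO replicate 2 at 20 µM. Leaving out any of these 3 libraries ended the calls of panB, groL and MMAR_RS01140 (highest adjusted p 0.281, 0.309 and 0.247), as leaving out DMSO replicate 1 at 20 µM or either compound library at 10 µM did. The call of clpB was lost without compound replicate 1 (0.0587), MMAR_RS10720 without DMSO or compound replicate 2 at 20 µM (0.0944), MMAR_RS28315 without DMSO or compound replicate 1 at 20 µM (0.0572), and ffs without either DMSO library at 20 µM, either compound library at 10 µM or compound replicate 1 at 20 µM (0.219). By voom clpB did not pass at 20 µM (adjusted p = 0.0523), and without rescaling panB, groL and MMAR_RS01140 did not (adjusted p = 0.251, adjusted p = 0.334 and adjusted p = 0.0653). On the implied fragments used by voom, clpB was at 0.54, against 0.95 in the main fit.

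The responses at 20 µM and 10 µM were then compared by testing their difference. The groL gene at 913752 responded in opposite directions, with a difference of -1.12 ± 0.13 (20 minus 10 µM, adjusted p = 0.0195), and leuC, which rose at 10 µM, had a difference of -1.11 ± 0.13 (adjusted p = 0.0195). MMAR_RS10720 fell further at 10 µM (difference 1.71 ± 0.28, adjusted p = 0.0414). lon, arsB and trxB were lower in response at 20 µM by differences of -0.75 ± 0.22, -0.98 ± 0.17 and -0.80 ± 0.14 that did not pass (adjusted p = 0.151, adjusted p = 0.0510 and adjusted p = 0.0510). For clpB the difference was -0.15 ± 0.16 (adjusted p = 0.693), and for panB 0.13 ± 0.17 (adjusted p = 0.757). By camera the ESX-3 list differed with a median of 0.60 (adjusted p = 0.000144), ESX-1 with 0.30 (adjusted p = 0.000436), ESX-5 with 0.19 (adjusted p = 0.0154), heat shock with -0.72 and ribosomal proteins with 0.24 (both adjusted p = 0.00254). Over all genes, 0 members of these ESX and ribosomal protein lists passed, and 1 of 3 heat shock genes did. Adjusted over the list alone, 1 ESX-3, 3 ESX-1 and 2 heat shock genes passed. For the Clp protease, arabinogalactan and Sec lists, which did not pass, the median, mean and test of the difference did not share a sign. With an estimated correlation the 5 lists became adjusted p = 0.524 for the ESX lists and adjusted p = 0.209 for the other 2, and by fry the heat shock list alone passed (adjusted p = 0.00499).

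In all, 51 genes differed in response: 16 rose more and 15 fell more at 10 µM, 19 had opposite signs (counting MMAR_RS04750, listed at 0 throughout the 10 µM comparison), and 1, MMAR_RS15735, was at 1.14 at 20 µM and 0.15 at 10 µM and was named after its values were seen. Of the calls at 20 µM, 87 genes were higher at both concentrations, against 7.07 for independent lists of these sizes, and 34 were lower at both, against 5.85. The lists are not fully independent, because both comparisons use the same estimate of the spread for each gene, which can add to the overlap. Another 3 genes rose at 10 µM and fell at 20 µM, namely groL at 913752 and, chosen after their values were seen, MMAR_RS01275 (0.84 and -1.02) and MMAR_RS05560 (0.46 and -0.56). In DMSO alone MMAR_RS01275 was itself higher at the 20 µM label, by 1.30 (adjusted p = 0.00285). Across the 5611 genes, which are not independent replicates, the changes correlated with Pearson r = 0.368 and Spearman rho = 0.332. Of the genes changed at 10 µM, 81.8% had the same sign at 20 µM, with a median ratio of the changes (20 over 10 µM) of 0.302. The count of 51 was 2 without DMSO replicate 1 at 20 µM, 10 without DMSO replicate 2 at 20 µM, 7 and 4 without compound replicates 1 and 2 at 20 µM, 9 without compound replicate 2 at 10 µM, and 30 and 122 without DMSO replicates 1 and 2 at 10 µM. The calls of groL and leuC were lost without either 20 µM DMSO library, either 20 µM compound library or compound replicate 2 at 10 µM (highest adjusted p 0.0907 and 0.100). That of MMAR_RS10720 was lost without any 1 of the 8 libraries (0.147), and the difference of MMAR_RS15735 without the same 5 libraries as groL (0.134). MMAR_RS01275 lost its rise without compound replicate 2 at 10 µM (0.0794) and its fall without any 20 µM library (0.112), and MMAR_RS05560 its rise without any library except DMSO replicate 1 at 10 µM (0.169) and its fall without any except the 10 µM DMSO libraries (0.311). The 121 shared calls were 80 and 69 without DMSO replicates 1 and 2 at 20 µM, 54 and 67 without compound replicates 1 and 2 at 20 µM, and 80 without compound replicate 2 at 10 µM.

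**Figure D4:**
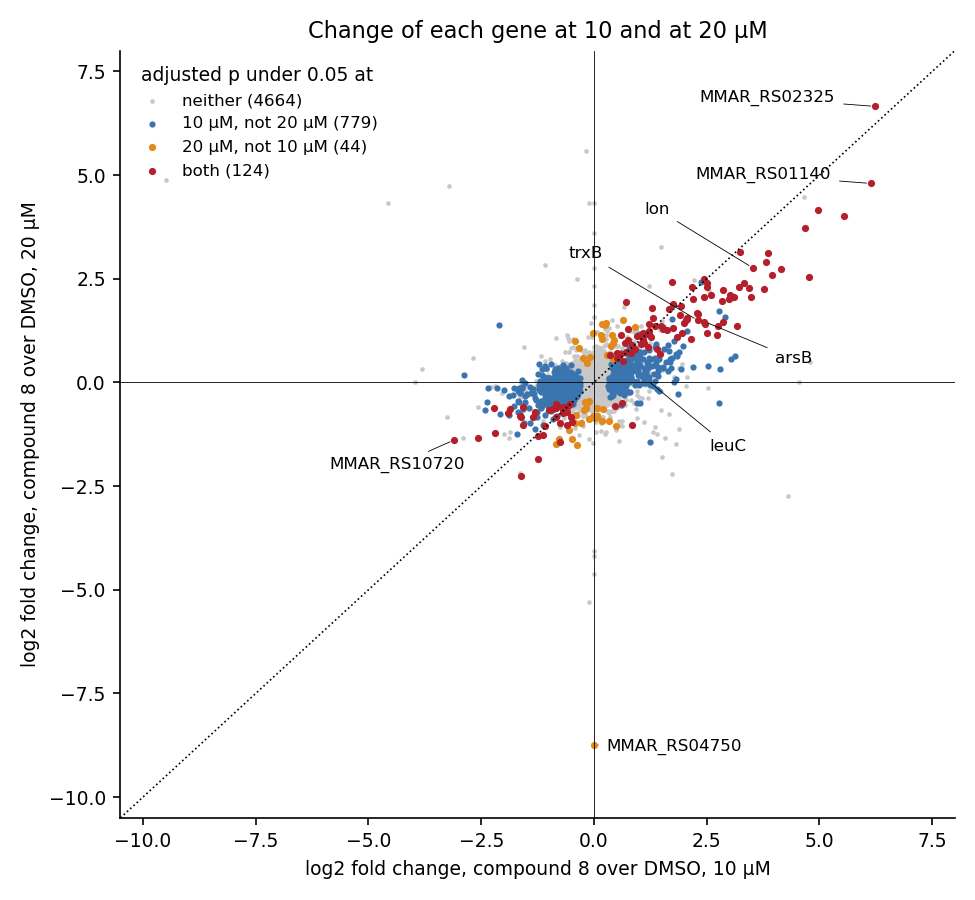
Log2 fold change of each tested gene (compound 8 over DMSO) at 10 µM on the horizontal and at 20 µM on the vertical axis, with the dotted line marking equal change and colours marking where adjusted p was under 0.05. Of the genes, 124 passed at both concentrations, 779 at 10 µM and not at 20 µM, and 44 at 20 µM and not at 10 µM.

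The DMSO groups give the background for both comparisons, since no compound was present. Ribosomal protein genes were lower in the DMSO cultures labelled 20 µM: 11 of 16 fell, 13 when adjusted over the list alone (median -0.95, adjusted p = 1.08e-10, adjusted p = 0.0362 with an estimated correlation). The largest falls with a symbol were rpmB at 332664 (363 ± 188 to 34.5 ± 8.15, which fell by 3.27 ± 0.37, adjusted p = 0.00320) and rpsR at 331924 to 332187 (fell by 2.93 ± 0.37, adjusted p = 0.00517). The rpmB copy at 2092492 was at -0.33 ± 0.29 and did not pass (adjusted p = 0.506). The S8 gene rpsH (1275215 to 1275613) fell by 1.60 ± 0.12, rpsR at 74400 fell by 1.54 ± 0.12 and rplS fell by 1.27 ± 0.13. Among the largest rises were the mycofactocin synthesis genes mftE (1249065 to 1249817, 0.89 ± 0.15) and mftF (1249814 to 1251226, 0.76 ± 0.08). The nitrite reductase gene nirD (610821 to 611177) rose by 0.89 ± 0.19, phoU at 1497403 to 1498068 by 0.78 ± 0.19, and cysE (4492776 to 4493462), of cysteine synthesis, by 0.71 ± 0.11. Genes named above also differed between the DMSO groups: trxB (fell by 0.52 ± 0.10), the trxA beside it (fell by 0.51 ± 0.12), panB (fell by 0.94 ± 0.12), the ESX-3 eccA (fell by 0.91 ± 0.11), recA (fell by 0.88 ± 0.14), lepB (fell by 0.75 ± 0.12), leuC (rose by 0.45 ± 0.09) and katG (rose by 0.57 ± 0.10). So did MMAR_RS10720 (fell by 1.09 ± 0.20), gltD (fell by 0.37 ± 0.09), the ESX-5 eccE (rose by 0.47 ± 0.12) and mycP (rose by 0.33 ± 0.08), and MMAR_RS04750, from an estimated 2 fragments per 20 µM DMSO library. The same was true of MMAR_RS28315 (rose by 1.63 ± 0.30), MMAR_RS01275 (rose by 1.30) and MMAR_RS15735 (fell by 0.36, adjusted p = 0.0490). lon, arsB and clpB did not pass, at 0.25 ± 0.15, 0.06 ± 0.12 and 0.00295 ± 0.11.

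Between the DMSO groups 709 genes differed, 256 higher and 453 lower at the 20 µM label (36.1% higher), 195 of them by at least 2-fold. Of the 903 genes changed at 10 µM, 257 (28.5%) also differed between the DMSO groups, against 114 for independent lists of these sizes. Of the 168 at 20 µM, 53 (31.5%) did, against 21.2. Each compound comparison shares its DMSO libraries with this one, so some overlap arises from the shared controls alone. The shared estimate of the spread for each gene can add to it. No other list passed camera between the DMSO groups (adjusted p = 0.193 to 0.945), while the cytochrome, TCA cycle and Sec and Tat export lists passed fry (each adjusted p = 0.0202, medians of -0.26, -0.21 and -0.05, the last of which turned to 0.13 without rescaling and 0.02 with upper-quartile scaling). For heat shock, Clp protease, sulfur and redox genes the median, mean and test did not share a sign. The split of higher and lower calls moved with the scaling, to 57.1% higher of 406 genes without rescaling and 52.0% higher of 757 with upper-quartile scaling. The count was 241 and 325 without DMSO replicates 1 and 2 at 20 µM, and 471 and 470 without compound replicates 1 and 2 at 20 µM, where the spread is estimated from fewer libraries. The gene nirD lost its call without either 20 µM DMSO library or DMSO replicate 2 at 10 µM (highest adjusted p 0.128), phoU without any library except DMSO replicate 1 at 10 µM (0.144), and cysE without DMSO replicate 1 at 20 µM (0.0565). By voom mftF (adjusted p = 0.253) and nirD (adjusted p = 0.131) did not pass. On the implied fragments mftF was at 0.32, against 0.76 in the main fit, and nirD at 0.91, against 0.89. The calls of trxB (0.0958) and katG (0.0681) were lost without either 20 µM DMSO library, and that of recA (0.0611) without DMSO replicate 1 at 20 µM. That of leuC (0.101) was lost without either 20 µM DMSO library or DMSO replicate 1 at 10 µM, and that of the trxA beside trxB (0.157) without either 20 µM library of DMSO or compound or DMSO replicate 2 at 10 µM. MMAR_RS10720 (0.0846) lost its call without DMSO replicate 2 at 10 µM or DMSO replicate 1 at 20 µM, and gltD (0.153) without any library except the 10 µM compound libraries. The ESX-5 eccE (0.200) lost it without any except DMSO replicate 1 at 10 µM, and mycP (0.157) and MMAR_RS15735 (0.188) without any 1 of the 8. MMAR_RS28315 (0.0891) lost it without either 20 µM DMSO library or DMSO replicate 1 at 10 µM.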

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

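The tests of explanations in this part were all chosen after the results they concern had been seen, while the test of the difference between the responses was planned.

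Responses at 20 and 10 µM differed by the test of the difference itself for 4 genes under the naming rule: leuC (-1.11), groL at 913752 (-1.12), MMAR_RS10720 (1.71) and MMAR_RS04750. The fitted -8.74 of MMAR_RS04750 depends on the pseudocount and is no bound, since it is listed at 0 in all but the DMSO libraries labelled 20 µM, where an estimated 2 fragments stand behind each value; by voom its change at 20 µM did not pass (adjusted p = 0.257). The difference also passed for 3 genes named after their values were seen, MMAR_RS01275 (-1.85), MMAR_RS05560 (-1.02) and MMAR_RS15735 (0.99), each lost without 5 or more of the 8 libraries left out in turn (highest adjusted p 0.0952, 0.180 and 0.134). By camera, 5 lists also differed: ESX-3 (median 0.60), ESX-1 (0.30), ESX-5 (0.19), heat shock (-0.72) and ribosomal proteins (0.24). Of their members, 1 heat shock gene passed over all genes, and 0 of the ESX and ribosomal protein lists did. None of the 5 lists passed with an estimated correlation (adjusted p = 0.209 to 0.524), and by fry the heat shock list alone did (adjusted p = 0.00499). The leuC and groL calls did not hold without either 20 µM DMSO library, either 20 µM compound library or compound replicate 2 at 10 µM (highest adjusted p 0.100 and 0.0907), nor that of MMAR_RS10720 without any 1 of the 8 libraries (0.147).

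Changes were smaller at 20 µM than at 10 µM. Choosing genes by their change at 10 µM would give such a pattern by itself, but over 829 genes called on the mean of both changes the median excess at 10 µM was 0.361 (0.323 to 0.497 with 1 library left out), although over genes called at 20 µM the median difference in size was -0.000184. The replicate spread was similar at both concentrations (ratio 1.04, 20 over 10 µM). This ratio does not decide about the spread, since the fit gives each gene the same SE at both concentrations. The scaling is argued against by at least 3.94 times as many genes changed at 10 as at 20 µM under 3 other scalings. Open and untested are the concentration itself and the separate set of cultures, which cannot be told apart because each concentration has its own cultures and DMSO libraries.

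The transfer-messenger RNA gene ssrA, outside the comparisons, had no estimate in 4 of 4 compound libraries and 1 of 4 DMSO libraries (Fisher exact two-sided p = 0.143). Where it had an estimate, it was listed at 439009 to 631836 FPKM, from an estimated 502186 to 949268 fragments. A missing estimate is not a value of 0 and does not show that ssrA was absent. Depth does not decide between explanations, because its measures differ. By implied totals the 5 libraries without an estimate are the deepest, by a gap of only 0.0797 M (mega) fragments. The other measure, estimated fragments summed over tested genes, was added after that gap was seen. By it, DMSO replicate 1 at 10 µM, which has an ssrA estimate (3.72 M), lies above both 10 µM compound libraries, which have none (3.54 and 3.71 M). Depth and compound 8 both stay open, and a change of ssrA under compound 8 was not tested.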

How the results depend on the processing

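Counts stayed within 1.5 times their values under median-of-ratios and upper-quartile scaling, no filter, ribosomal RNA genes kept and pseudocounts of 0.1 and 5. Genes changed at 10 µM came to 475 with only the 4 libraries compared, which leave fewer samples for the spread, and genes differing between the DMSO groups to 276. Without rescaling these were 496 and 406, and the cause of the lower counts was not tested. The median of all genes was then 0.11 at 10 µM and 0.18 between the DMSO groups, against -0.00472 and 0.00801 in the main fit. Genes whose response differed came to 144 by voom and 95 among genes of at least 200 bp, and the cause was not tested. Of the lists, 0 passed at 10 µM and 0 at 20 µM with an estimated correlation (2 and 0 at unadjusted p under 0.05), and at 20 µM 1 passed by fry (Clp protease and proteasome, none of the 3 that passed camera) and 0 by voom, where the cause was not tested. With 1 library left out, counts ranged from 407 to 792 at 10 µM, 68 to 208 at 20 µM, 2 to 122 for the difference, 241 to 729 for the DMSO groups and 54 to 137 for the overlap, and lists from 3 to 5 at 10 µM and 0 to 3 at 20 µM. For named genes, 1086 alternatives kept direction and call, 144 lost the call and 0 reversed, and for lists 599 kept it, 22 lost it and 4 gained it. Apart from left-out libraries and the block, the gene calls were lost as follows. Without rescaling they were, at 10 µM, the ESX-3 eccB, eccD, eccE and mycP, the ESX-5 eccD, eccE and mycP, panB, rpsR at 74400, groL at 1349333 and gltD, and at 20 µM panB, groL at 913752 and MMAR_RS01140. With only the 4 libraries compared they were, at 10 µM, merA, rpmB, rplS, rpsR, gltD, groL at 1349333, the ESX-3 eccB, eccE and mycP and the ESX-5 eccE and mycP, at 20 µM groL at 913752 and MMAR_RS01140, and between the DMSO groups mftE, nirD and phoU. By voom they were the ESX-3 eccA, the ESX-5 eccD, eccE and mycP and gltD at 10 µM, clpB and MMAR_RS04750 at 20 µM, and nirD and mftF between the DMSO groups. A loss by voom does not decide about a gene whose implied fragments do not follow its FPKM, such as the ESX-3 eccA. Upper-quartile scaling ended the call of the ESX-5 eccE at 10 µM and a pseudocount of 0.1 that of MMAR_RS01140 at 20 µM. Depth limits genes with few fragments, such as MMAR_RS04750 (2 in each library where it is listed above 0), MMAR_RS01140 (at most 2 in a DMSO library), rpmB at 332664 (10.1) and ffs (38.9). The planned DESeq2 fit was not run, since it needs counts, and a fit on 4 libraries gives no value for the difference.

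Whether replicate numbers pair the libraries is open. Correlations of the deviations from the group means had both signs, from -0.26 to 0.21 between groups, so a shared replicate effect was neither shown nor excluded. With the replicate number as a block, the counts were 711 at 10 µM, 118 at 20 µM, 22 for the difference and 547 for the DMSO groups. The block ended the calls of the ESX-5 eccE and mycP and groL at 1349333 at 10 µM (adjusted p = 0.0508, 0.0556 and 0.0521), of ffs, panB, groL at 913752 and MMAR_RS01140 at 20 µM (0.0629, 0.0958, 0.0823 and 0.0905), of phoU between the DMSO groups (0.0633) and of the ribosomal protein list at 20 µM (0.0530), and the cause was not tested.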

Other observations

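The tests of runs, of the plasmid and of explanations in this part were chosen after the values had been seen, while the comparison of the DMSO groups was planned.

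Genes changed at 10 µM lay side by side more often than in shuffled gene orders. There were 35 runs of at least 4 neighbouring genes changed in the same direction (201 genes, 14 runs higher and 21 lower), against at most 4 in 1000 shuffles (permutation p = 0.000999, the smallest they can give). Neighbouring genes often share a transcript, so they are not independent. At 20 µM there were 2 runs, of 7 genes each, at 3218299 to 3223507 (median 2.31 at 10 µM and 1.66 at 20 µM) and 4376577 to 4382534 (2.87 and 2.24), and all 14 genes were higher at both concentrations. A run of 7 genes at 2983451 to 2990520, with the arginine synthesis genes argB and argF, was higher at 10 µM (median 0.68, and 0.06 at 20 µM). The longest run, of 13 genes at 4532123 to 4557012, was lower (median -1.39, and -0.15 at 20 µM). All 13 of its genes were also lower in the 20 µM than in the 10 µM DMSO cultures (median -0.90). A run of 8 genes with rplS and lepB at 2197715 to 2203169 was lower (median -0.72, and -0.33 at 20 µM), and 7 of the 8 differed between the DMSO groups (median -0.84). These DMSO differences share the 10 µM DMSO libraries with the changes at 10 µM and the 20 µM ones with the changes at 20 µM, so the 3 values are not independent.

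On the plasmid, 9 of 28 genes rose at 10 µM and 0 fell by limma (2 were lower at unadjusted p under 0.05, and 1 by voom), with a median of 0.22 against -0.00543 on the chromosome. They include 2 runs of 4 genes, at 12901 to 15868 with merA (median 1.14) and at 16219 to 18095 (0.91). At 20 µM 1 plasmid gene rose and 1 fell. Neighbouring copies of ribosomal protein genes at 331924 to 332900 were at -1.18 ± 0.37 (rpsR, adjusted p = 0.0798), -1.08 ± 1.26 (rpmG, adjusted p = 0.628, from an estimated 7 to 28 fragments) and -1.89 ± 0.37 (rpmB, adjusted p = 0.0160) at 10 µM. Of the copies elsewhere, rpsR at 74400 fell by 0.63 ± 0.12. The copies of rpmG at 1181408 (-0.16 ± 0.24, adjusted p = 0.706) and rpmB at 2092492 (-0.30 ± 0.29, adjusted p = 0.546) did not pass. Between the DMSO groups rpmG did not pass (adjusted p = 0.0536), with an estimated 28 and 10 fragments in the 10 µM DMSO libraries and 1 and 0 in the 20 µM ones.

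The DMSO groups differed in 709 genes with no compound present. Library depth is argued against by a correlation of 0.488 over genes between 2 differences that share no library and whose depths differ by 3.93 and -2.09 M (mega) fragments. Scaling is argued against as the whole cause by 406 genes that differed without rescaling, the fewest under 3 other scalings, of which 360 were among the 709. A different growth state may contribute, since ribosomal protein genes were lower at the 20 µM label (median -0.95), but growth was not measured in the values used here. The labelled amount of DMSO and the set of cultures cannot be told apart, because the libraries of a label share both.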
